A study of Mus musculus with 12 samples.

How the data were processed

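The samples were hepatocytes isolated from the livers of male C57BL/6J mice aged 8 to 10 weeks, by perfusion with Liberase, differential centrifugation and a Percoll step, per the labels' protocols. Alb-Cre mice carry the Cre recombinase under the albumin promoter and served as controls, and Alb-R3 mice are labelled as having the receptor gene Fgfr3 deleted in hepatocytes. Mice received olive oil alone or carbon tetrachloride (CCl4), a liver toxicant, at 0.4 mg per g body weight in olive oil, and RNA was taken 48 h later. The 12 samples form 4 groups of 3: Alb-Cre oil, Alb-R3 oil, Alb-Cre CCl4 and Alb-R3 CCl4. The labels number the samples of a group 1 to 3 without saying that each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

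The authors deposited a table of 35709 Ensembl gene identifiers, of which 35574 matched a gene symbol and 135 did not. The submitters' processing notes name kallisto 0.44.0, edgeR without a version and the genome build GRCm38.p6, without saying which step each served. For each sample the deposited table holds a normalized count and an FPKM value, per the file headers. The deposited normalized count behaves as an estimated count divided by a single factor per sample, a signal and not a count of whole reads: among low values, between 69.9% and 74.4% per sample were whole multiples of what 1 read is worth, with a tolerance of 0.02. The deposited FPKM values follow from the normalized counts by gene length and library total. Over 4242 genes with values above 500 in each sample, the length implied by the 2 columns varied between samples by a coefficient of variation of 0.0187% (median) and at most 0.0418%. From the value of 1 read, the depth of the samples was between 28000000 and 39600000 estimated reads, so counting error is small for all but the lowest genes and the spread between samples sets the precision.

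The design fixed before the data were examined was edgeR's quasi-likelihood test on counts (estimated counts rounded), or limma on a log scale if the values were normalized and not counts. As the deposited values were normalized, the second was used. Estimated counts, the values divided by that of 1 read, were not put through a count model. Values were analysed as log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, in 1 model with a coefficient for each of the 4 groups and 8 residual degrees of freedom. The 20244 genes with a value of at least 1 in at least 3 samples were tested. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and errors of fold changes are limma's standard errors (SE). Adjusted p-values are limma's, with Benjamini-Hochberg adjustment over the tested genes within a comparison, and the threshold was 0.05. The 5 comparisons were CCl4 against oil in each genotype, Alb-R3 against Alb-Cre after each treatment, and the difference between the genotypes in their response to CCl4 (the interaction).

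Gene lists were tested with limma's camera at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the 40 lists within a comparison. They were 27 lists of pathways and liver functions and 13 lists of cell type markers, each with at least 5 tested members. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. Camera was also run with a correlation estimated from the data, and fry, which asks whether the genes of a list move in 1 direction on balance, was run beside it.

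The genes named were chosen by a rule: Fgfr1, Fgfr2, Fgfr3, Fgfr4 and Klb throughout; in each comparison the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold with no overlap between the groups and a mean of at least 5 in the higher group, leaving out predicted and clone-named models; where fewer than 5 passed, the 5 genes of smallest p (no overlap was required for the interaction); and, for each list past the threshold or with at least 3 members past it, the 2 members of largest fold in each direction. Not each gene the rule takes is printed. Lists, rule, comparisons and most alternatives were fixed before the data were examined. Gene positions are those of GENCODE M21 on GRCm38, 1-based.

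The alternatives were quantile normalization, limma without the trend, no filter and a stricter filter on low values (at least 6 samples), pseudocounts of 0.1 and 5, the replicate number as a block, other thresholds, a fit to the 6 samples compared, and leaving out each sample in turn. Library weights (limma's array weights) and the FPKM columns (pseudocount 0.1) were chosen after seeing the data. So was the closer look at the lists without Alb-R3 CCl4 replicate 1, a fit already held by the planned leaving out of each sample. Replicate pairs were compared with counting noise, which they exceeded in each of the 12 pairs (mean squared difference 39.0 to 974.6 times the noise), so no pair was taken as 1 library.

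The procedure was tested on simulated data with the overall mean and the spread (capped) of each real gene. There were 200 changed genes among 20244, drawn from those with a mean above 20. Noise was independent between genes and of equal size in each library, with counting noise added. Correlated genes and a library set apart like Alb-R3 CCl4 replicate 1 were not simulated, so the rates may differ in the real data. For CCl4 in Alb-Cre, 41 of 100 genes changed 2-fold and 76 of 100 changed 4-fold were called, with 9 unchanged genes called. For the genotypes after oil these numbers were 41, 79 and 7, and for the interaction 5, 49 and 8.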

Results

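RNA-seq of isolated hepatocytes was compared between Alb-Cre control mice and mice labelled as hepatocyte Fgfr3 knockouts (Alb-R3), 48 h after oil or CCl4, with 3 samples in each of the 4 groups. Totals of normalized counts ran from 27200000 to 38800000 per sample and depth from 28000000 to 39600000 estimated reads. The first principal component held 37.0% of the variance and separated CCl4 from oil, and the second held 16.2%. The library Alb-R3 CCl4 replicate 1 lay far from the other libraries of its group: mitochondrially encoded genes took 32.3% of its normalized counts, against 7.22% and 7.85% in the other 2 and 6.22% to 12.8% in the remaining 9 libraries. Its share of Alb, the albumin gene, was 3.19% against 8.14% and 8.58%, and that of the Kupffer cell and macrophage markers was 0.0446% against 0.0113% and 0.0158%.

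**Figure D1:**
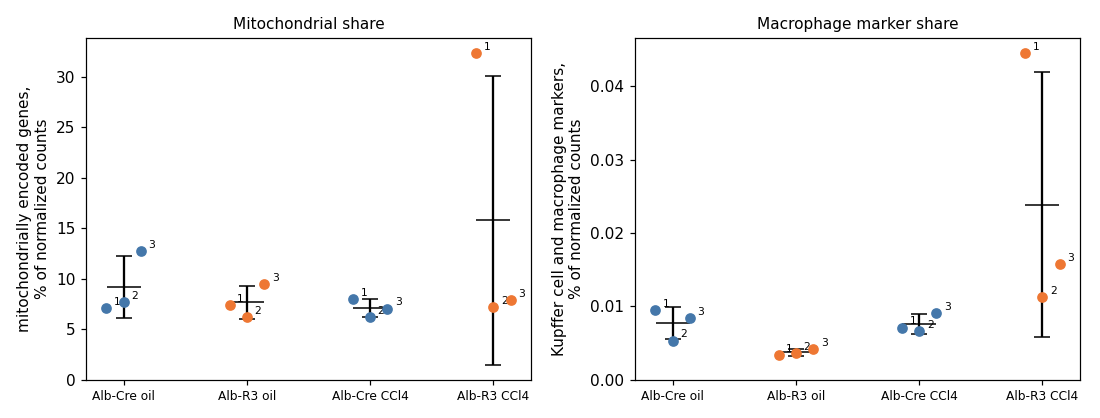
Share of normalized counts taken by mitochondrially encoded genes (left, percent) and by Kupffer cell and macrophage markers (right, percent) in each of the 12 libraries, by group. Points are libraries, numbered by replicate, and bars give the group mean with 1 SD; Alb-R3 CCl4 replicate 1 has the highest value in both panels, 32.3% and 0.0446%.

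Fgfr3 itself (ENSMUSG00000054252, chromosome 5, 33721674 to 33737068) was measured in each library first, since it is the gene labelled as knocked out. After oil, its normalized count was 734.9, 887.6 and 988.1 in the Alb-Cre libraries and 523.1, 650.5 and 1109 in those labelled Alb-R3, so the library labelled Alb-R3 oil replicate 3 had the highest value of the 12. After CCl4 it was 950.9, 705.7 and 753.0 in Alb-Cre and 477.7, 372.1 and 382.3 in Alb-R3. The log2 difference between the genotypes was -0.26 ± 0.24 (SE, n = 3 per group) after oil and -0.96 ± 0.24 after CCl4, and neither passed the test over all genes (adjusted p = 1 and 0.252). That adjustment counts all tested genes, although Fgfr3 was named in advance. After CCl4 the 3 Alb-R3 values lay below the 3 Alb-Cre values. With library weights, chosen after seeing the data, the difference after CCl4 passed (-1.07, limma adjusted p = 0.0435). From oil to CCl4, Fgfr3 fell by 0.82 ± 0.24 in Alb-R3 (adjusted p = 0.034) and changed by -0.12 ± 0.24 in Alb-Cre (adjusted p = 0.868), while the interaction was -0.71 ± 0.34 (adjusted p = 0.702). The call in Alb-R3 was lost without the library labelled Alb-R3 oil replicate 3 (-0.51, adjusted p = 0.122), without Alb-R3 oil replicate 2 (adjusted p = 0.061), without Alb-R3 CCl4 replicate 2 (0.0886) and without Alb-R3 CCl4 replicate 3 (0.0849). The value is 1 per gene, and which exons were deleted is not given in the sources used here, so transcripts lacking them may still be counted. The other receptors Fgfr1, Fgfr2 and Fgfr4 and the co-receptor Klb passed in none of the 5 comparisons with all 12 samples (smallest adjusted p 0.176, for Fgfr2 with CCl4 in Alb-Cre; without Alb-Cre CCl4 replicate 3 it passed, with a log2 change of -1.07 and adjusted p = 0.0244).

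**Figure D2:**
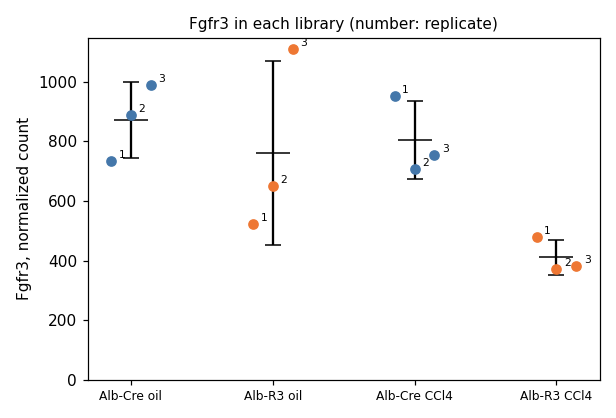
Normalized count of Fgfr3 in each of the 12 libraries, by group. Points are libraries, numbered by replicate, and bars give the group mean with 1 SD; the 3 Alb-R3 CCl4 libraries lie between 372.1 and 477.7, below the Alb-Cre CCl4 libraries, and the library labelled Alb-R3 oil replicate 3 lies at 1109.

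The response of control hepatocytes to CCl4 was asked in the Alb-Cre libraries. Genes of cell division were the most strongly raised. All 30 members of the mitosis list passed the test upward, with a median log2 fold change of 5.92, as did 28 of 30 members of the DNA replication list (30 adjusted over the list alone) with a median of 3.46. Camera gave adjusted p = 6.65e-48 and 1.42e-46, and 0.0617 and 0.0554 with an estimated correlation. Cdc20, an activator of the anaphase-promoting complex, went from a normalized count of 8.96 ± 6.68 (SD, n = 3) to 2003 ± 1097, a log2 fold change of 7.72 ± 0.78 (SE). The proliferation marker Mki67 rose by 7.60 ± 0.53, the topoisomerase Top2a by 7.55 ± 0.53 and Uhrf1, which maintains DNA methylation at replication, by 7.46 ± 0.59. Hmmr, Racgap1, Dlgap5, Iqgap3, Ckap2l and Plk1 made up the rest of the 10 largest increases, between 7.29 and 7.63.

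In the p53 list 3 of 25 members rose (7 adjusted over the list alone; camera adjusted p = 0.00188, and 0.377 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a at 4.18 ± 0.33 (62.0 ± 25.3 to 1112 ± 380) and Phlda3 at 3.23 ± 0.52. Of the 23 measured fetal and progenitor genes, 8 rose and none fell, and 12 rose adjusted over the list alone (median 1.22). This list kept its call with an estimated correlation (camera adjusted p = 2.68e-09 and, estimated, 0.0125). Among them were Ly6d (5.98 ± 0.68) and alpha-fetoprotein, Afp (4.22 ± 0.51, from 19.96 ± 7.1 to 391 ± 135). In the list of profibrotic ligands and matrix remodelling 5 of 29 genes rose (7 adjusted over the list alone, median 0.91, adjusted p = 0.000214, and 0.162 with an estimated correlation), among them the plasminogen activator Plat at 3.45 ± 0.60 and osteopontin, Spp1, at 3.26 ± 0.72. The call of Spp1 was lost without Alb-Cre oil replicate 3 (adjusted p = 0.0848), Alb-Cre CCl4 replicate 1 (0.0766) or Alb-Cre CCl4 replicate 2 (0.0838). In the chemokine list 3 of 24 rose (6 rose and 1 fell adjusted over the list alone; adjusted p = 0.0468, and 0.694 with an estimated correlation). The call of this list was lost without Alb-Cre oil replicate 1 (0.0756), Alb-Cre oil replicate 3 (0.0798) or Alb-Cre CCl4 replicate 2 (0.103). None of the 26 unfolded protein response genes passed over all genes, and 9 rose and 2 fell adjusted over the list alone (adjusted p = 0.0188, and 0.68 with an estimated correlation). That call was lost without Alb-Cre oil replicate 3 (0.169) or Alb-Cre CCl4 replicate 2 (0.29). Markers of stellate cells and fibroblasts moved with these groups: 5 of 18 rose (8 adjusted over the list alone, median 0.78, adjusted p = 2.03e-05, and 0.433 with an estimated correlation), including the collagen gene Col1a1 at 3.70 ± 0.54 (5.33 ± 0.98 to 81.8 ± 18.7) and the actin gene Acta2, listed at 0 in the 3 Alb-Cre oil libraries and at 17.5, 50.3 and 9.97 after CCl4. Kupffer cell markers did not pass (0 of 16; adjusted p = 0.284), nor did those of endothelial cells (0 of 16; adjusted p = 0.0562). Kupffer cell markers passed as lower without Alb-Cre oil replicate 2 (0.0492), and endothelial markers as higher without Alb-Cre oil replicate 3 (0.00752) or Alb-Cre CCl4 replicate 2 (0.00137).

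Among the 200 genes that fell were genes of hepatocyte metabolism. Slc1a2, a glutamate transporter of pericentral hepatocytes, fell by 7.74 ± 0.39 (751.6 ± 91.5 to 2.54 ± 0.71), and Oat, the ornithine aminotransferase, fell by 3.41 ± 0.38 (8612 ± 3501 to 778 ± 205). Of 30 pericentral genes 4 fell and 1, Slc1a4, rose (7 and 1 adjusted over the list alone; adjusted p = 0.00181, and 0.631 with an estimated correlation). In the list of urea cycle, amino acid and glucose metabolism 2 of 30 fell, Sds (-1.83 ± 0.34) and the glycine methyltransferase Gnmt (-1.75 ± 0.31), and 8 adjusted over the list alone (adjusted p = 7.11e-07, and 0.558 with an estimated correlation). Periportal genes had 1 fall, Sds, and 1 rise, Apoa4 (2.77 ± 0.49), with 6 and 2 adjusted over the list alone (adjusted p = 0.000214, and 0.583 with an estimated correlation). In the list of cytochromes P450 and phase II enzymes 3 of 40 fell (4 adjusted over the list alone; adjusted p = 0.00333, and 0.68 with an estimated correlation), such as Cyp2d22 at -0.84 ± 0.15. In fatty acid synthesis 2 of 23 did (adjusted p = 0.0114, 0.631 with an estimated correlation and 0.234 without Alb-Cre CCl4 replicate 2). Its called members Lpin1 and Dgat2 lost the call without Alb-Cre oil replicate 1 (limma adjusted p = 0.0615 and 0.112). They also lost it without Alb-Cre oil replicate 2 (0.0529 and 0.124) or Alb-Cre CCl4 replicate 2 (0.0626 and 0.0663). The lists of bile acid genes, plasma proteins and male-biased genes had 0 members past the threshold (limma; also 0 adjusted over the list alone) and medians of -0.30, -0.25 and -0.60. Camera gave adjusted p = 0.0122, 0.00306 and 0.0217, and 0.68, 0.584 and 0.68 with an estimated correlation. The bile acid call was lost without Alb-Cre CCl4 replicate 2 (0.103) and that of plasma proteins without Alb-Cre CCl4 replicate 3 (0.0633). The median of plasma proteins was -0.39 without Alb-Cre CCl4 replicate 2. Male-biased genes were no longer called without Alb-Cre oil replicate 1 (0.0752), Alb-Cre oil replicate 2 (0.205) or Alb-Cre CCl4 replicate 2 (0.103), and their median was -0.38 without Alb-Cre CCl4 replicate 3. Mup17, of the major urinary proteins, fell by 6.07 ± 0.87 and the acute phase gene Orm3 by 3.47 ± 0.66. The Mup genes are near-identical copies whose reads the counting could split, so values of single members are uncertain.

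In all, 900 of 20244 genes passed, 700 higher and 200 lower after CCl4, and 702 of them changed at least 2-fold. Quantile normalization gave 548 higher and 233 lower, and the FPKM columns 1096 and 88. Library weights gave 2703 genes. The FPKM columns and the weights were chosen after seeing the data. The count was 523 without Alb-Cre CCl4 replicate 2, 576 without Alb-Cre oil replicate 1 and 590 without Alb-Cre CCl4 replicate 3. It was 1393 without Alb-R3 CCl4 replicate 1, which enters this comparison only through the spread.

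The same contrast in the Alb-R3 libraries asked how the hepatocytes labelled as knockout respond. Genes of cell division again led: 30 of 30 mitosis genes (median 6.59) and 29 of 30 DNA replication genes (median 3.00) passed upward, also adjusted over the list alone. Camera gave adjusted p = 3.94e-32 and 7.04e-27, and 0.13 for each with an estimated correlation. Foxm1, a transcription factor of the G2 and M phases, rose by 8.28 ± 0.53 (1.12 ± 1.10 to 661 ± 337), cyclin B1, Ccnb1, by 8.28 ± 0.88 and Ckap2l by 8.31 ± 0.82. Sprr1a and the helicase gene Pif1 were listed at 0 in the 3 Alb-R3 oil libraries. After CCl4 Sprr1a stood at 169.2, 276.9 and 311.8 and Pif1 at 117.6, 268.8 and 391.1.

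Fetal and progenitor genes rose in 14 of 23 cases (16 adjusted over the list alone, median 1.81; adjusted p = 3.03e-10, and 0.00893 with an estimated correlation), among them Ly6d (7.70 ± 0.68) and Prom1 (6.92 ± 0.72, 0.78 ± 0.67 to 247 ± 202). In the list of profibrotic ligands and matrix remodelling 14 of 29 rose (18 rose and 1 fell adjusted over the list alone; adjusted p = 2.9e-07, and 0.0838 with an estimated correlation). In the chemokine list 14 of 24 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 7.26e-06, and 0.269 with an estimated correlation). Spp1, in both, rose by 5.07 ± 0.72 and stood at 5354 in Alb-R3 CCl4 replicate 1 against 1020 and 389.5 in the other 2. Timp1, an inhibitor of metalloproteinases, was listed at 0 after oil and at 86.7, 10.99 and 26.4 after CCl4. Of 31 interferon response genes 6 rose (7 adjusted over the list alone), such as Oas1a (2.91 ± 0.48); the list had adjusted p = 0.00254, 0.486 with an estimated correlation, and 0.251 without Alb-R3 CCl4 replicate 1. The unfolded protein response list had 9 of 26 rising (12 rising and 2 falling adjusted over the list alone; adjusted p = 0.00691, and 0.486 with an estimated correlation), led by asparagine synthetase, Asns (3.17 ± 0.42). Asns rose from a level that was lower in Alb-R3 than in Alb-Cre after oil (-3.32 ± 0.42). After CCl4 its log2 difference from Alb-Cre was -0.99 ± 0.42. The p53 list had 8 of 25 rising (9 adjusted over the list alone; adjusted p = 0.00141, and 0.208 with an estimated correlation), led by Phlda3 (4.58 ± 0.52) and Cdkn1a (4.07 ± 0.33). Of 21 YAP targets 9 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.025, 0.203 with an estimated correlation and 0.0514 without Alb-R3 CCl4 replicate 2), with Ccn2 at 3.66 ± 0.49. The FGF list did not pass as a whole (adjusted p = 0.128, and 0.0484 without Alb-R3 oil replicate 2), with 8 of 24 members rising, led by the phosphatase gene Dusp5 (4.12 ± 0.59), and 1, Fgfr3, falling.

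Markers of several other liver cells rose too. All 16 Kupffer cell and macrophage markers passed upward (median 2.32, adjusted p = 5.19e-09, and 0.255 with an estimated correlation). So did 7 of 10 monocyte markers (9 adjusted over the list alone; adjusted p = 5.52e-05, and 0.269 with an estimated correlation). Of the endothelial markers 13 of 16 passed (16 adjusted over the list alone, median 1.30; adjusted p = 9.67e-09, and 0.209 with an estimated correlation), and of the stellate cell markers 13 of 18 (16 adjusted over the list alone, median 2.09; adjusted p = 4.58e-10, and 0.144 with an estimated correlation). Cd68 rose by 3.08 ± 0.42 and Lyve1, an endothelial receptor, by 2.47 ± 0.34. Without Alb-R3 CCl4 replicate 1, 12 Kupffer cell markers (median 1.58), 4 monocyte markers, 15 endothelial and 17 stellate cell markers passed. Marco stood at 1621 in that library and at 115.7 and 146.7 in the other 2. Cholangiocyte markers had 4 of 9 rising (6 adjusted over the list alone; adjusted p = 0.0112, and 0.144 with an estimated correlation) and dendritic cell markers 1 of 7 (adjusted p = 0.0271, 0.39 with an estimated correlation, 0.11 without Alb-R3 CCl4 replicate 1, 0.0505 without Alb-R3 CCl4 replicate 3 and 0.0514 without Alb-R3 oil replicate 1). Hepatocyte markers had 2 of 12 falling (adjusted p = 0.0071, and 0.255 with an estimated correlation).

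Among the 1400 genes that fell were genes of hepatocyte metabolism. Cyp2e1, the cytochrome that activates CCl4, fell by 4.43 ± 0.77 (190600 ± 28580 to 14470 ± 11270), and its value in Alb-R3 CCl4 replicate 1 was 1562 against 19460 and 22390. Slc1a2 fell by 7.11 ± 0.39 and Cyp7b1, of bile acid synthesis, changed by -3.38 ± 0.47. Of the pericentral genes 15 of 30 fell and 1 rose (18 and 1 adjusted over the list alone; median -1.21, adjusted p = 4.65e-07, and 0.269 with an estimated correlation). Of the periportal genes 9 of 30 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 5.52e-05, and 0.297 with an estimated correlation), with Pck1, of gluconeogenesis, at -2.44 ± 0.40. In the list of cytochromes P450 and phase II enzymes 14 of 40 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 3.25e-06, and 0.377 with an estimated correlation). In the bile acid list 7 of 26 fell and 2 rose (14 and 2 adjusted over the list alone; adjusted p = 9.56e-05, and 0.357 with an estimated correlation). In the urea cycle list 12 of 30 fell (16 adjusted over the list alone; adjusted p = 1.23e-08, and 0.269 with an estimated correlation). Of the plasma proteins 9 of 34 fell (12 adjusted over the list alone; adjusted p = 8.38e-08, and 0.208 with an estimated correlation). Of the hepatocyte identity factors 4 of 25 fell (4 adjusted over the list alone; adjusted p = 0.00524, and 0.208 with an estimated correlation), among them Cebpa (-1.30 ± 0.30). Male-biased liver genes had 12 of 19 falling (14 adjusted over the list alone; median -2.06, adjusted p = 1.77e-07, and 0.255 with an estimated correlation), such as Susd4 (-4.80 ± 0.52) and Hsd3b5 (-4.06 ± 0.87). Fatty acid synthesis (3 of 23 falling, 1 rising) and fatty acid oxidation (3 of 30 falling; 0 adjusted over the list alone) had adjusted p = 0.025 and 0.0167, which became 0.486 and 0.567 with an estimated correlation and 0.261 and 0.223 without Alb-R3 CCl4 replicate 1. Fatty acid oxidation also lost its call without Alb-R3 oil replicate 2 (0.0568). Without Alb-R3 CCl4 replicate 1 the medians of pericentral, periportal and cytochrome P450 genes moved from -1.21, -0.79 and -0.82 to -0.73, -0.31 and -0.35, still past the threshold.

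The remaining lists did not pass in Alb-R3. Adjusted p was 0.0595 for cholesterol synthesis and 0.191 for the NRF2 response (8 of 30 rising, 1 falling), and without Alb-R3 CCl4 replicate 1 these were 0.00244 and 0.00383. Cholesterol synthesis also passed without Alb-R3 oil replicate 2 (0.0387). It was 0.437 for the acute phase response (3 of 32 rising, 3 falling; 0.0263 without that library) and 0.199 for female-biased genes (0.0124 without it). It was 0.105 for the circadian clock (5 of 21 falling, 1 rising; 0.0378 without Alb-R3 oil replicate 1), 0.126 for immediate-early genes and 0.221 for the Wnt pathway. Among markers it was 0.0595 for neutrophil (0.00943 and 0.0187 without Alb-R3 CCl4 replicates 2 and 3), 0.134 for T and NK cell, 0.993 for B and plasma cell, 0.828 for erythroid, 0.221 for platelet and 0.848 for mesothelial markers.

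**Figure D3:**
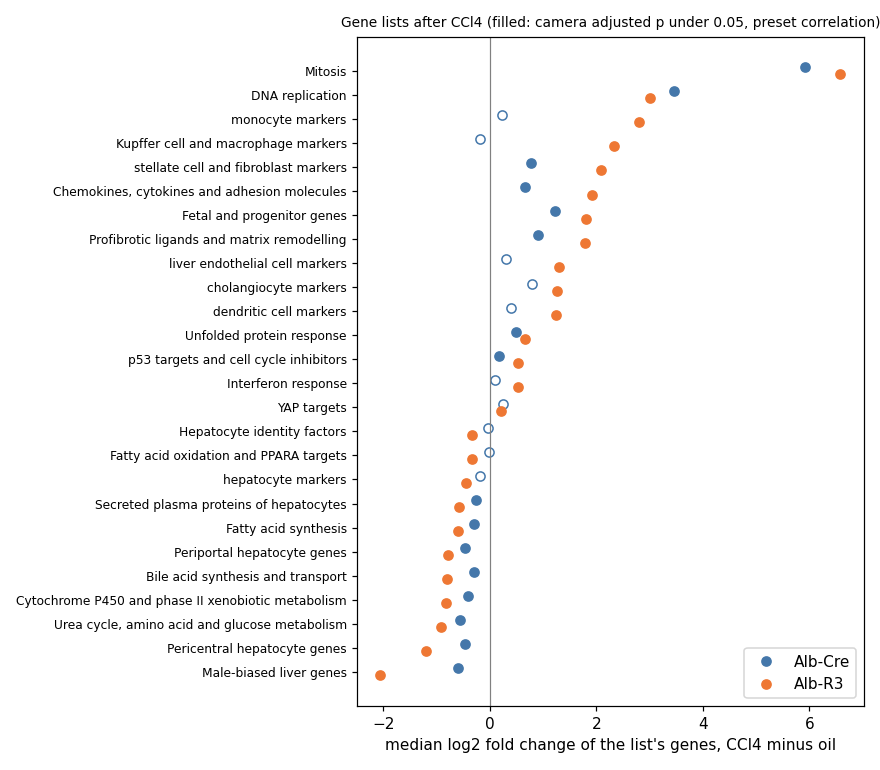
Median log2 fold change after CCl4 of the genes of each list that passed in Alb-R3, for Alb-Cre and Alb-R3. Filled points passed camera at the preset correlation and open points did not; the mitosis list has the highest median in both genotypes, 5.92 and 6.59.

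In all, 3598 genes passed in Alb-R3, 2198 higher and 1400 lower. The split depended on the scaling: quantile normalization gave 1729 higher and 1644 lower, and the FPKM columns, chosen after seeing the data, 3118 and 544. Fitting only the 6 samples compared gave 2039 genes. Of the genes called in Alb-Cre, 628 of the 700 higher and 172 of the 200 lower were called the same way in Alb-R3, where independent lists would share 76.0 and 13.8, and 0 genes were called in opposite directions. Across 9602 genes with a mean above 100 the fold changes correlated between the genotypes with Pearson's r = 0.796 (across genes, which are not independent replicates). The count in Alb-R3 was 3174 without Alb-R3 CCl4 replicate 1, 2119 without Alb-R3 oil replicate 1 and 2299 without Alb-R3 oil replicate 2. In the fit without Alb-R3 CCl4 replicate 1, pericentral genes had 9 members falling in Alb-Cre and 13 in Alb-R3, adjusted over all genes. Periportal genes had 7 and 8, cytochromes P450 7 and 9, and the urea cycle list 9 and 10. A wider gap stayed for bile acid genes (3 and 7), plasma proteins (1 and 9) and male-biased genes (2 and 10).

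Whether the response itself differed between the genotypes was tested as an interaction. Limma called 0 of 20244 genes (smallest adjusted p 0.247), with 1516 genes (7.49%) at an unadjusted p under 0.05 and 6 genes called by limma without the trend, so with equal library weights the larger count in Alb-R3 is not a difference shown gene by gene. Library weights, chosen after seeing the data, called 46 genes, and leaving out 1 library gave 0 to 3 (3 without Alb-R3 CCl4 replicate 1, 2 without Alb-Cre oil replicate 3 or Alb-R3 CCl4 replicate 3). The smallest p belonged to Npr2, a natriuretic peptide receptor, at -1.85 ± 0.27 (adjusted p = 0.247). Its level was 1124 ± 78 and 297 ± 66 (SD, n = 3) in Alb-Cre oil and CCl4, and 2029 ± 193 and 148 ± 32 in Alb-R3. Next were Cd93 (2.40 ± 0.40), Anxa2 (2.28 ± 0.42), Tagln2 (1.66 ± 0.32) and Epb41l2 (1.46 ± 0.29), each with adjusted p = 0.364. Gene lists gave 21 past the threshold at the preset correlation and 0 with an estimated correlation or by fry, where the smallest adjusted p was 0.137 with an estimated correlation, for fetal and progenitor genes.

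The genotypes were then compared after oil, the state before injury. Cebpe, a transcription factor of granulocytes (chromosome 14, 54710360 to 54712174), stood at 232.0, 261.5 and 263.7 in Alb-Cre and was listed at 0 in the 3 Alb-R3 libraries. Nuggc (chromosome 14, 65598546 to 65648531) was listed at 0 in the 3 Alb-Cre libraries and stood at 39.4, 69.1 and 95.8 in Alb-R3. Lnx1, a ubiquitin ligase, was lower in Alb-R3 by -4.51 ± 0.42 (233.8 ± 103.0 against 9.41 ± 4.85) and Acpp by -6.44 ± 0.70. Klhl33 was higher by 4.36 ± 0.37 (3.69 ± 0.69 against 94.8 ± 8.9) and Poln, a DNA polymerase gene at 34007179 to 34169448 on chromosome 5 and near Fgfr3, by 4.98 ± 0.55. Asns was lower by -3.32 ± 0.42 (282 ± 120 against 28.0 ± 15.02), and its log2 difference after CCl4 was -0.99 ± 0.42 (adjusted p = 0.586). Olfr149 was listed at 0 in Alb-Cre and at 27, 40.7 and 36.4 in Alb-R3. Pglyrp1 was listed at 0 in Alb-Cre and at 10.9, 19.3 and 21.3 in Alb-R3. Ebf1 stood at 18.1, 19.5 and 18.2 in Alb-Cre and was listed at 0 in Alb-R3.

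Marker lists of endothelial, stellate and Kupffer cells were lower in Alb-R3 after oil at the preset correlation, with 1 member past the threshold over all genes. Of 16 endothelial markers 1 passed over all genes, Ptprb (-1.26 ± 0.22; adjusted p = 0.0415, and 0.0967 to 0.152 when any 1 of the 6 libraries was left out), and 14 adjusted over the list alone, with a median of -1.02 (adjusted p = 1.68e-17, and 0.451 with an estimated correlation). Stellate cell markers had 0 and 8 of 18 lower (median -0.92; adjusted p = 1.62e-09, and 0.452 with an estimated correlation) and Kupffer cell markers 0 and 1 of 16 (median -1.03; adjusted p = 1.41e-08, and 0.704 with an estimated correlation). The other 9 marker lists of non-hepatocytes did not pass (adjusted p = 0.38 to 0.951), among them dendritic cells (0.38), monocytes (0.49) and cholangiocytes (median 0.02, 0.666). Hepatocyte markers did not pass (median -0.03, adjusted p = 0.951). The cholesterol synthesis list was higher (25 of 26 members with a positive sign, 0 past the threshold, median 0.34; adjusted p = 0.000281, and 0.93 with an estimated correlation), with a median of 0.60 without Alb-Cre oil replicate 1. Its call was lost without Alb-Cre oil replicate 2 (0.0741) or Alb-Cre oil replicate 3 (0.0601). The mitosis list gave adjusted p = 0.38 and the FGF list 0.082. The FGF list passed as lower without Alb-Cre oil replicate 2 (0.0372), Alb-R3 oil replicate 1 (0.0329) or Alb-R3 oil replicate 2 (0.00957). In all 42 genes passed, 20 higher and 22 lower in Alb-R3, out of 1314 at an unadjusted p under 0.05. The count was 28 without Alb-Cre oil replicate 2 and 28 without Alb-R3 oil replicate 2. It was 102 without Alb-R3 CCl4 replicate 1, which enters this comparison only through the spread. Library weights, chosen after seeing the data, gave 663 genes (270 higher, 393 lower), and fitting only the 6 samples compared gave 12 (8 higher, 4 lower). The weights of replicates 1, 2 and 3 were 3.66, 0.834 and 0.376 in Alb-Cre oil and 2.11, 1.04 and 0.679 in Alb-R3 oil. In the weighted fit replicate 1 thus carried the largest share of each of these group means.

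After CCl4 the genotypes differed in 35 genes, 17 higher and 18 lower in Alb-R3, out of 1573 at an unadjusted p under 0.05. Several were those of the oil comparison: Cebpe (-6.42 ± 0.52), Acpp (-5.76 ± 0.70), Lnx1 (-3.39 ± 0.42), Klhl33 (3.30 ± 0.37), Nuggc (3.95 ± 0.53) and Igsf23 (2.98 ± 0.36). In all 17 genes passed in both treatments, each in the same direction, where independent lists would share 0.0726. Others passed after CCl4 only, although their interaction did not: A2ml1, a protease inhibitor, was higher by 3.05 ± 0.42 (252 ± 184 against 1828 ± 649), the NADPH oxidase gene Nox4 lower by -2.02 ± 0.27 (650 ± 11 against 168 ± 71) and the steroid dehydrogenase gene Hsd3b2 by -1.67 ± 0.23 (2533 ± 416 against 801 ± 192; adjusted p = 0.00865, and 0.0554 without Alb-Cre CCl4 replicate 1). Cyp4a12b, a male-biased cytochrome, was lower by -4.27 ± 0.58, but 62.9% of its 31-base words occur in another gene, so its share of reads is uncertain, as are those of Tmem254b (100%) and Hsd3b2 (37.6%).

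Male-biased genes were lower as a list, with 2 of 19 past the threshold (9 adjusted over the list alone, median -1.58; adjusted p = 1.05e-08, and 0.301 with an estimated correlation). Female-biased genes were higher (0 of 24, 4 adjusted over the list alone, median 1.07; adjusted p = 6.44e-05, and 0.357 with an estimated correlation). Kupffer cell markers were higher (0 of 16 over all genes, 13 adjusted over the list alone, median 1.58; adjusted p = 1.06e-12, and 0.301 with an estimated correlation). Monocyte markers were higher too (0 of 10, 5 adjusted over the list alone, median 1.79; adjusted p = 2.87e-07, and 0.301 with an estimated correlation). Endothelial markers did not pass (median 0.01, adjusted p = 0.845). Chemokines (median 0.74, adjusted p = 3.52e-07, and 0.301 with an estimated correlation) and interferon response genes (median 0.60, adjusted p = 1.98e-09, and 0.301 with an estimated correlation) were higher with them, with 0 members past the threshold over all genes. Fetal and progenitor genes had 0 of 23 past it and 5 adjusted over the list alone (median 0.60; adjusted p = 3.52e-07, and 0.0347 with an estimated correlation). The preset correlation gave 21 lists in all and an estimated correlation 1. Without Alb-R3 CCl4 replicate 1 the medians of Kupffer cell and monocyte markers were 0.83 and 0.92, and those of chemokines and interferon response genes 0.40 and 0.27, still past the threshold. Lists that passed at the preset correlation without it but not with it were mitosis (median 1.03, adjusted p = 2.17e-10), the NRF2 response (7.54e-07), p53 targets (0.00298), endothelial markers (median 0.22, 0.0224) and stellate cell markers (0.000189). In that fit 0 of their members passed over all genes, and an estimated correlation was not run. Mean log2 levels of mitosis genes were 9.73 and 9.97 in Alb-R3 CCl4 replicates 2 and 3. They were 9.24 to 9.29 in Alb-Cre CCl4 replicates 1 and 3 but 7.98 in replicate 2. Without Alb-R3 CCl4 replicate 1 adjusted p became 0.638 for pericentral genes, 0.672 for cytochromes P450, 0.626 for bile acid genes, 0.129 for the urea cycle list, and 0.152 for DNA replication. It became 0.873 for the Wnt pathway, 0.626 for neutrophil markers, 0.0706 for T and NK cell markers and 0.214 for hepatocyte markers. These 9 had passed with that library at the preset correlation, and with an estimated correlation gave adjusted p = 0.301 to 0.478. The median of T and NK cell markers without it was 0.75, the highest of the 6 fits without 1 library, while that of neutrophil markers was 0.18. The mean log2(value + 1) of T and NK cell markers was only 0.86 to 1.93 over the 12 libraries, near the floor. Without Alb-R3 CCl4 replicate 3 female-biased genes lost their call (0.0943) and the median of male-biased genes was -1.03. Pericentral genes lost theirs without Alb-Cre CCl4 replicate 3 too (0.0727), hepatocyte markers without Alb-Cre CCl4 replicate 2 (0.0906) and neutrophil markers without Alb-Cre CCl4 replicate 1 (0.0592).

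The counts of genes were 20, 21 and 23 without Alb-Cre CCl4 replicates 3, 1 and 2, and 21 without Alb-R3 CCl4 replicate 3. Library weights and the FPKM columns, both chosen after seeing the data, gave 103 and 54 genes, and fitting only the 6 samples compared gave 2.

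**Figure D4:**
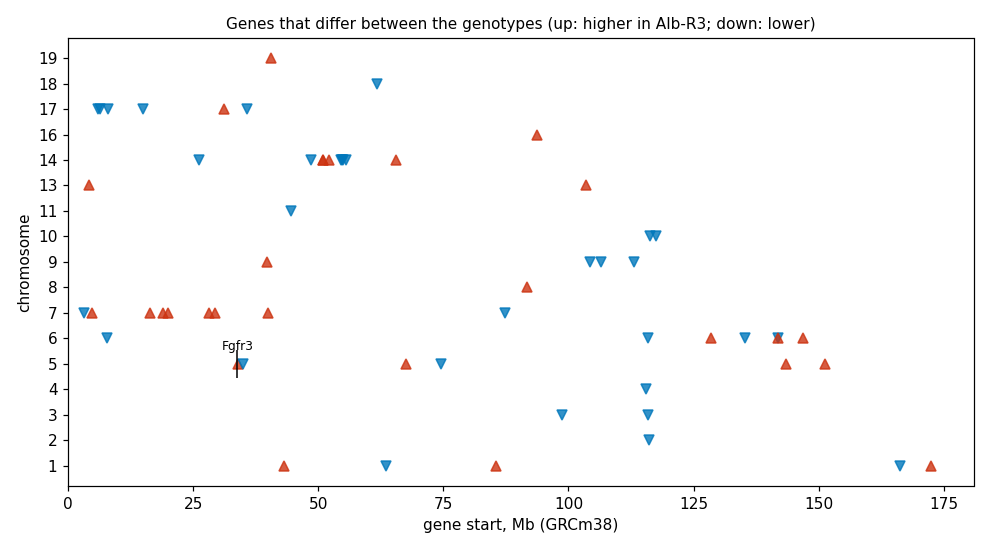
Positions of the 60 genes that differed between the genotypes after oil or after CCl4, along the chromosomes of GRCm38 (Mb). Upward and downward triangles mark genes higher and lower in Alb-R3 and the bar marks Fgfr3; chromosome 14 holds 10 of them and chromosome 7 holds 9.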

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

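The tests on lower Fgfr3 itself, on the library Alb-R3 CCl4 replicate 1 (alone, mislabelled, diluted or damaged), on the share of hepatocytes, with library weights and with size-matched windows were chosen only after the result was seen.

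The test of the interaction drew attention to 21 gene lists past camera's threshold at the preset correlation. They are given with the median difference in log2 response (Alb-R3 minus Alb-Cre), which camera does not itself test. They were mitosis 0.52, pericentral genes -0.48, cytochromes P450 and phase II enzymes -0.55, bile acid genes -0.55, the urea cycle list -0.36, chemokines 0.96, interferon response 0.53, YAP targets 0.24, profibrotic genes 0.89, fetal and progenitor genes 0.76, plasma proteins -0.45, male-biased genes -1.67, female-biased genes 0.97 and the Wnt pathway -0.22. Among markers they were Kupffer cells 2.44, monocytes 2.16, neutrophils 2.38, endothelial cells 1.04, stellate cells 0.95, T and NK cells 1.16 and dendritic cells 1.57. With an estimated correlation 0 passed (adjusted p = 0.137 to 0.646). Relabelling genotype within treatment gave as many lists in 10 of 100 cases, the real one included, with up to 27, so chance cannot be excluded. Without Alb-R3 CCl4 replicate 1, adjusted p was 0.202 for pericentral genes, 0.609 for cytochromes P450, 0.576 for bile acid genes, 0.789 for the urea cycle list, 0.142 for interferon response, 0.661 for the Wnt pathway, 0.291 for neutrophil, 0.0799 for T and NK cell and 0.194 for dendritic cell markers. In that fit the median of T and NK cells stayed at 1.15, while that of neutrophils was 0.515 and that of the Wnt pathway -0.02. T and NK cell markers lay near the floor, with mean log2(value + 1) of 0.86 to 1.93 over the 12 libraries, so their median is uncertain. Cholesterol synthesis (0.00269) and the NRF2 response (5.62e-05) passed without Alb-R3 CCl4 replicate 1 but not with it, with 0 members past the threshold over all genes. Among lists that stayed past the threshold, the medians of chemokines (0.35), monocytes (0.98) and mitosis (1.17) moved by over 1.5 times, beside Kupffer cells 1.74, endothelial cells 1.25, stellate cells 1.29 and male-biased genes -1.35. The 9 lists that passed in each fit without 1 library were chemokines, profibrotic genes, fetal and progenitor genes, plasma proteins, male-biased genes and the Kupffer cell, monocyte, endothelial and stellate cell markers. Endothelial and stellate cell markers differed between the genotypes after oil, while their levels after CCl4 overlapped. Mean log2 levels of endothelial markers were 8.1 to 8.5 in Alb-Cre oil and 7.1 to 7.5 in Alb-R3 oil. After CCl4 they were 8.2 to 8.8 in each genotype. Stellate cell markers stood at 5.3 to 5.5 and 4.3 to 4.7 after oil. After CCl4 these were 6.4 to 6.7 in Alb-Cre and 6.0 to 7.1 in Alb-R3. Mitosis was lost without Alb-Cre oil replicate 1 (0.172), Alb-R3 oil replicate 1 (0.0742) or 2 (0.0728), Alb-Cre CCl4 replicate 2 (0.553), and Alb-R3 CCl4 replicate 2 (0.368) or 3 (0.519). YAP targets were lost without Alb-Cre oil replicate 1 (0.116) or 2 (0.0638), the library labelled Alb-R3 oil replicate 3 (0.106), and Alb-R3 CCl4 replicate 2 (0.0856) or 3 (0.0528). Without Alb-Cre oil replicate 3 the urea cycle list (0.192), female-biased genes (0.0707), the Wnt pathway (0.157), neutrophils (0.0644) and dendritic cells (0.247) were lost. Without Alb-R3 CCl4 replicate 3 female-biased genes (0.368) and dendritic cells (0.093) were lost. Without Alb-Cre CCl4 replicate 3 bile acid genes (0.0925), the Wnt pathway (0.0528) and neutrophils (0.0617) were lost. The Wnt pathway was also lost without Alb-R3 oil replicate 2 (0.103) and neutrophils without Alb-Cre CCl4 replicate 1 (0.0594). Dendritic cells were lost without Alb-R3 oil replicate 1 (0.0604) or 2 (0.0559), and Alb-Cre CCl4 replicate 1 (0.0559) or 2 (0.0821). Other medians that moved by over 1.5 times were those of chemokines without Alb-Cre CCl4 replicate 2 (1.49) or Alb-R3 CCl4 replicate 2 (1.45), monocytes without Alb-R3 CCl4 replicate 2 (3.35) and stellate cells without Alb-R3 CCl4 replicate 3 (0.59). So did plasma proteins without Alb-Cre oil replicate 3 (-0.27) or Alb-Cre CCl4 replicate 2 (-0.28), T and NK cells without Alb-Cre oil replicate 3 (0.68), YAP targets without Alb-R3 oil replicate 1 (0.39) or 2 (0.14) and the Wnt pathway without the library labelled Alb-R3 oil replicate 3 (-0.37), Alb-R3 CCl4 replicate 2 (-0.40) or 3 (-0.45).

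For genes, limma's real interaction count was 0 (1516 at an unadjusted p under 0.05; 6 without the trend, 46 with library weights), and the highest other was 2. Any of the 100 splits reaches 0, so this decides nothing. The 10 splits of 6 samples are too few for a share under 0.05. The real count and the highest of the other splits were 900 and 1 for CCl4 in Alb-Cre, 3598 and 3 in Alb-R3, 42 and 2 for the genotypes after oil, and 35 and 0 after CCl4. For gene lists at the preset correlation they were 16 and 19, 26 and 24, 4 and 8, and 21 and 23, and 3, 1, 6 and 3 of the 10 splits, the real one included, gave as many lists.

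The 60 genes that differed between the genotypes lay close together: 29 had another of them within 5 Mb, against a median of 16 and a highest of 34 in 10000 random sets matched on expression, of which 0.23% were as high. Reads shared between near-identical genes are argued against as the whole cause, since the median gene shares 3.64% of its 31-base words with another, although 6 share over 50%. DNA of another strain carried along with the genotype is a candidate explanation: over 808 neighbouring genes not themselves called, the genotype differences after oil and after CCl4 correlated with r = 0.278 across genes, as high as in 0 of 1000 window sets elsewhere and in 15 of 1000 size-matched sets. Of the 60 genes, Poln (34007179 to 34169448) and Msantd1 (34908012 to 34923839) lay near Fgfr3 on chromosome 5, while chromosome 14 held 10. Lower Fgfr3 itself stays open, as 34 of 35 separating genes lay nearer Alb-R3 in the library labelled Alb-R3 oil replicate 3, which decides nothing while the deleted exons are unknown.

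More genes passed after CCl4 in Alb-R3 than in Alb-Cre, by 2698. The library Alb-R3 CCl4 replicate 1 alone is argued against as the whole cause. In the fit without it 3174 genes passed in Alb-R3 and 1393 in Alb-Cre, 2.28 times as many, against 4 times with it. With 1 Alb-Cre CCl4 library left out as well the ratio was 2.58, 3.63 and 2.9 for replicates 1, 2 and 3. With library weights 5117 and 2703 passed. A lower share of hepatocytes in the Alb-R3 CCl4 libraries cannot be told apart from other causes. Kupffer cell markers rose by 0.94 more than endothelial markers (standard error 0.81), which does not measure the share of hepatocytes itself. Without Alb-R3 CCl4 replicate 1, which carried most of the value, this was 0.13 with a standard error of 0.16. In Alb-R3 CCl4 replicates 1, 2 and 3 hepatocyte markers took 6.16%, 11.8% and 12.2% of counts. They took 11.6% to 12.1% in Alb-Cre CCl4 and 9.07% to 11.1% in Alb-R3 oil, so replicates 2 and 3 show no lower share. Their mean log2 level in replicates 2 and 3 was 16.4, however, against 16.5 to 16.6 in Alb-Cre CCl4 and 16.9 to 17.0 in Alb-R3 oil. A response that depends on the genotype remains possible, since only 2 of 100 relabellings, the real one included, gave a difference as large (median 748, highest other 2709), but 0 genes passed the interaction (1516 at an unadjusted p under 0.05; 6 by limma without the trend, 46 with library weights) and the endothelial, stellate and Kupffer cell marker lists that differed after oil at the preset correlation enter the count too.

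Alb-R3 CCl4 replicate 1 stood apart, with 32.3% mitochondrial counts. A mislabelled genotype is argued against, since 7 of 39 separating genes lay nearer Alb-Cre. Dilution by RNA of other cells is argued against as the whole cause, because hepatocyte markers did not fall by a common factor: the SD of their log2 ratios to the other 2 libraries was 1.42, against 0.228 between those 2, from Cyp2e1 at -3.74 to Fgb at 1.14. Damaged cells or RNA could not be decided: its deviations from its group correlated across genes with r = 0.252 with those of Alb-Cre oil replicate 3, the library of next highest mitochondrial share (12.8%), but with r = 0.275 with those of Alb-Cre CCl4 replicate 2, whose share was 6.25%. No biological explanation of this library was tested.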

How the results depend on the processing

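The library weights, the FPKM columns and the counts without a library from outside the comparison were chosen only after the result was seen. The closer look at the lists without Alb-R3 CCl4 replicate 1 was too, although that fit was planned. The other alternatives were planned. Each gene called in the 4 two-group comparisons kept its direction in each alternative fit that tested it. Limma without the trend, the replicate block and the fit to the 6 samples compared leave fold changes as they were, so these could not alter a direction. Library weights gave 2703 genes for CCl4 in Alb-Cre, 663 and 103 for the genotypes after oil and CCl4, 46 for the interaction, 7 lists after oil, and Fgfr3 after CCl4 past the threshold at -1.07 (adjusted p = 0.0435, against 0.172 to 0.69 in the other alternatives). The weights ran from 0.217 (Alb-R3 CCl4 replicate 1) to 3.66 (Alb-Cre oil replicate 1), so the 3 libraries of a group did not count equally. The cause of the larger counts was not tested. Limma without the trend gave 6 for the interaction. The FPKM columns gave 54 genes for the genotypes after CCl4. With them the median log2 fold change of all genes after CCl4 was 0.15 in Alb-Cre and 0.16 in Alb-R3, against 0.02 and 0.00, and 92.6% and 85.1% of calls were higher, against 77.8% and 61.1%. Quantile normalization moved these shares the other way, to 70.2% and 51.3%. For the genotypes after oil, quantile normalization gave 60.5% higher against 47.6%. For the genotypes after CCl4, the FPKM columns gave 63.0% higher against 48.6%. An adjusted p under 0.01 gave 453 and 1602 genes for CCl4 and 27 and 14 for the genotypes, by construction. Fitting only the 6 samples compared gave 2039 for CCl4 in Alb-R3 and 12 and 2 for the genotypes, with fewer samples to estimate the spread. With an estimated correlation 1 list passed in Alb-Cre, 1 in Alb-R3, 0 after oil, 1 after CCl4 and 0 for the interaction, and by fry 8, 25, 0, 1 and 0. Leaving out 1 of the libraries compared gave 523 to 684 genes for CCl4 in Alb-Cre, 2119 to 3302 in Alb-R3, 28 to 43 and 20 to 38 for the genotypes after oil and CCl4, and 0 to 3 for the interaction. The lowest came without Alb-Cre CCl4 replicate 2, Alb-R3 oil replicate 1, Alb-Cre oil replicate 2 or Alb-R3 oil replicate 2, and Alb-Cre CCl4 replicate 3. Leaving out Alb-R3 CCl4 replicate 1, which enters only through the spread there, gave 1393 for CCl4 in Alb-Cre and 102 for the genotypes after oil. Over the genes named, 2710 results under alternatives stayed on their side of the threshold, 403 lost the call, 9 gained it and 0 changed sign while called. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated between -0.186 and 0.196, with 3 of 18 above 0.1, and the highest correlation between different numbers was 0.275. With the replicate number as a block the counts were 713, 3091, 37, 28 and 0. The DESeq2 and limma-voom alternatives were not run, because they need counts and the deposited values were normalized. Estimated counts, which could have been rounded for them, were used for depth and replicate pairs only. Simulated 2-fold changes of the interaction were called for 5 of 100 genes.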

Other observations

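The gene families below were chosen only after the result was seen, and so were the tests on them.

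Tubulin genes rose with CCl4 in both genotypes: 5 of 14 passed in Alb-Cre with 0 falling (median 1.21), and 9 rose and 1 fell in Alb-R3 (median 1.65). Camera gave adjusted p = 7.74e-08 and 2.13e-06, and 0.0353 and 0.0496 with an estimated correlation. Kinesins, the motors that move along microtubules, rose in 11 of 34 cases in Alb-Cre and in 14 of 34 in Alb-R3, where 2 fell (adjusted p = 3.74e-06 and 1.05e-05, and 0.0398 and 0.0496 with an estimated correlation). Some kinesins are also members of the mitosis list. Annexins had 1 of 10 rising in Alb-Cre (adjusted p = 0.0286, and 0.139 with an estimated correlation) and 6 of 10 in Alb-R3 (median 0.89; adjusted p = 0.00894, and 0.0597 with an estimated correlation). The difference between the genotypes in the response of annexins had adjusted p = 0.0218, and 0.255 with an estimated correlation.

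The major urinary proteins, secreted by male mouse liver, fell as a family. In Alb-Cre 5 of 22 passed (median -1.31; adjusted p = 5.51e-07, and 0.164 with an estimated correlation) and in Alb-R3 10 of 22 (median -1.89; adjusted p = 2.13e-06, and 0.188 with an estimated correlation). Of the 5 in Alb-Cre, Mup1 (limma adjusted p = 0.197), Mup5 (0.0642) and Mup9 (0.136) lost the call without Alb-Cre CCl4 replicate 2. The near-identical copies of this family make single members uncertain. Keratins had 3 of 12 rising in Alb-R3 and 0 in Alb-Cre. S100 genes had 3 of 10 rising and 2 falling in Alb-R3 and 1 rising in Alb-Cre. Neither family passed camera in Alb-Cre (keratins adjusted p = 0.936, S100 genes 0.967) or in Alb-R3 (0.181 and 0.169). For the interaction camera gave 0.0598 and 0.0176, and 0.257 and 0.482 with an estimated correlation. Proteasome subunits had 0 of 39 past the threshold in either genotype, with medians of -0.17 and -0.19 (adjusted p = 0.00325 and 0.0328, and 0.439 and 0.6 with an estimated correlation). Of 75 cytosolic ribosomal proteins 0 passed in Alb-Cre (median -0.16) and 1 in Alb-R3 (median 0.26). Camera gave this family adjusted p = 0.00618 and 0.00894, and 0.79 and 0.69 with an estimated correlation, and 1.01e-08 for the interaction (0.482 with an estimated correlation).

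Lcn2, an acute phase gene chosen after its values were seen, varied widely within groups. It stood at 31140 in Alb-R3 CCl4 replicate 1 against 1426 and 4195 in the other 2, and at 17440 in Alb-Cre CCl4 replicate 2 against 724.3 and 279.3. The neutrophil gene S100a8, chosen in the same way, stood at 376.6 in Alb-R3 CCl4 replicate 1 and at 7.33 and 2.40 in the other 2.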
